A study of Homo sapiens with 8 samples.

How the data were processed

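Ribosome-protected fragments and RNA were prepared from WM902B melanoma cells at passage 18 carrying shSCR or shTINCR, in 2 biological replicates per condition, per the labels' protocols. Cells were treated with cycloheximide (100 µg/ml, 5 min), which arrests elongating ribosomes, and footprints were made by RNase I digestion and sucrose gradient centrifugation with a commercial mammalian ribosome profiling kit, per the labels' protocols. Cycloheximide can itself shift footprints along an mRNA, most near the start codon. Dose and time were the same in both conditions, but whether the shift was the same in both was not tested. CASAVA 1.9, TopHat2 2.0.8, Bowtie2 2.1.0, SAMtools 0.1.18, HTSeq 0.5.3p9, DESeq 1.10.1 and genome build hg19 are named, without their roles, per the submitters' processing notes. Trimming, removal of ribosomal RNA reads, treatment of multi-mapping reads, the counted region and the filter on low values are not given in the sources used here.

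The authors' deposited table holds 1 comparison, shTINCR over shSCR, for 4616 genes. Its log2 columns are, per the file headers, the log2 TE of each condition and the log2 change of TE in 2 versions with a final choice between them. Its p-value columns are, per the file headers, a p-value for each version, the final p-value and an adjusted p-value. The tool that made these columns is not given in the sources used here. From the values, the final p-value was the larger of the 2 versions in all 4616 rows, taken from the first version in 2706. The 2 versions of the log2 change differed by at most 0.00794, and the second version equalled the difference of the deposited log2 TE values within 0.00873. The deposited adjusted p equalled a Benjamini-Hochberg adjustment over all rows to within 2e-15. No column held values of a library, so 0 of the 8 libraries could be analysed on their own. The planned count tests of mRNA, footprints and TE over all libraries were therefore not run, and the authors' changes and p-values are described in their place, as the design fixed before the data were examined provided for. The depth of the libraries and the spread between replicates are unknown. The precision of a single change is known only through the standard error that its log2 change and p-value imply. That standard error takes the p-value as that of a normal statistic. It was used only to filter and match genes and as the noise of the simulations described below. How a gene's TE change divides between footprints and mRNA cannot be told from the table.

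Genes were called at the deposited adjusted p below 0.05. Folds were computed as 2 to the power of the deposited log2 change. The genes named in the text follow a rule fixed before the data were examined: TINCR and ATF4, the 10 largest rises and falls among genes past the threshold, and from each gene list the 4 members with the smallest p plus up to 4 more past the threshold. This gave 133 genes, some of which are not reported here. A further 6 genes (MITF, RPS15, RPS26, RPS2, EIF4EBP1 and EIF2AK1) were named after their values were seen. Gene symbols were matched to the RefSeq gene table of GRCh38.p14, of which only names and the question which genes lie inside others were used: 4465 symbols were current, 139 were older names with a unique match and 12 had none. Symbols are printed as the table gives them.

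The 26 gene lists, covering stress responses, translation, cell cycle, melanoma cell states, metabolism and markers of other cell types, were also fixed before the data were examined. For each list the members past the threshold were counted, over all genes and with Benjamini-Hochberg over the list's members alone. The shift of a list against the other genes was tested with cameraPR of limma 3.58.1 (R 4.3.3, two-sided, preset correlation 0.01, Benjamini-Hochberg over 23 lists) on a z value made from the deposited p-value and the sign of the log2 change. Lists with fewer than 3 measured members were not tested. As a description, each list's median was placed among those of 10000 random lists of the same size, drawn also with matching in 20 bins on log2 TE in shSCR cells or on the standard error implied by the log2 change and its p-value, since the table has no column of expression level. All other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

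The list test and the threshold on single genes were tried on simulated data with 4616 genes, in 100 simulations per setting, with the implied standard errors as noise. Genes were drawn independently of each other, and a simulated list was called at an unadjusted p below 0.05. Of lists of 30 genes, 4% were called with no shift, 54% with a log2 shift of 0.1 and 99% with one of 0.2. These list percentages cover neither correlation between members of a list nor the adjustment over all tested lists. They are therefore not the rates of false or missed calls of the reported list test. Of single genes with a simulated log2 change of 0.25, 11.7% were called, and of those with 0.5, 68.7%. Unchanged genes made up 4.68% of calls. The simulated noise had exactly the standard errors that the simulated test used, so this share follows from the threshold of 0.05. It does not check the deposited p-values and is not the share of false calls among the reported genes.

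The alternatives tried were thresholds of 0.01 and 0.1 on the adjusted p, a minimum log2 change of 1, subtraction of the median of all genes, each version of the authors' estimate, restriction to genes with a small implied standard error, preset correlations of 0.05 and 0.1, ranks or the log2 change as the list statistic, lists without genes that another list holds, and the random lists. An enrichment search beyond these lists was limited to families of gene symbols.

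For the tests of explanations, a named pseudogene was a pseudogene of the RefSeq table whose symbol is the gene's symbol followed by P and a number. A small nucleolar RNA host was a gene whose span in that table holds such a gene on either strand, with a span found for 4604 of 4616 genes. These counts are of gene names and spans, and reads were not examined.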

Results

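Ribosome-protected fragments and RNA were sequenced from WM902B, a human cell line established from a primary melanoma with an activating BRAF mutation. The cells expressed either a scrambled control hairpin (shSCR) or a hairpin against TINCR (shTINCR), a long non-coding RNA known from epidermal differentiation. The 8 libraries formed 4 groups of 2 biological replicates each, 4 libraries of footprints and 4 of RNA. The values analysed here were those of 1 table in which the authors compared the hairpins gene by gene. For each of 4616 genes it gave the log2 translational efficiency (TE, footprints over mRNA) in each condition, the log2 change of TE and a p-value. The table held no value or error per replicate and no separate mRNA or footprint change, and the depth of the libraries is unknown. No interval was computed for any value.

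The comparison asked which mRNAs were translated more or less efficiently, relative to their abundance, when TINCR was targeted. The median log2 TE over all genes was close to 0 in both conditions (0.0078 in shSCR and 0.0019 in shTINCR cells). Each rise or fall is therefore relative to the typical gene, and a change of translation shared by all genes could not be seen. TINCR itself had 0 rows in the table, so its silencing was not checked here. TE of ATF4, the transcription factor of the integrated stress response, rose 1.99-fold in the authors' deposited table, from a log2 TE of -3.73 in shSCR to -2.74 in shTINCR cells (adjusted p = 1.37e-06). TE of CHAC1, a glutathione-degrading enzyme that ATF4 induces, rose 2.42-fold, and that of the ferritin light chain FTL rose 2.15-fold in the authors' deposited table. In the opposite direction, the elongation factors EEF2 and EEF1A1 fell to 0.453-fold and 0.481-fold of their shSCR TE in the authors' deposited table. As groups, the ATF4 and amino acid response genes shifted up, with 11 of 28 measured members past the threshold (adjusted p = 2.03e-05, camera). Ribosomal proteins and translation factors shifted down, with 39 of 75 and 19 of 44 measured members that fell (adjusted p = 3.64e-17 and 4.83e-17, camera). These 3 p-values rest on a preset correlation between genes of 0.01. With a correlation of 0.1 they were 0.0446, 0.000652 and 0.000136 (adjusted p, camera).

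At the authors' adjusted p below 0.05, TE of 757 genes (16.4%) changed, 380 upwards and 377 downwards, and 3859 genes did not pass. The median log2 change was 0.44 among the genes that rose (1.36-fold) and -0.39 among those that fell (0.764-fold). The median over all genes was 0.02, with an SD of 0.249 across genes. A log2 change of at least 0.5 was reached by 124 of the genes that rose and 77 of those that fell, and one of at least 1 by 4 genes in each direction. Across genes, which are not independent replicates, the log2 TE of the 2 conditions had a Pearson r of 0.963.

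**Figure D1:**
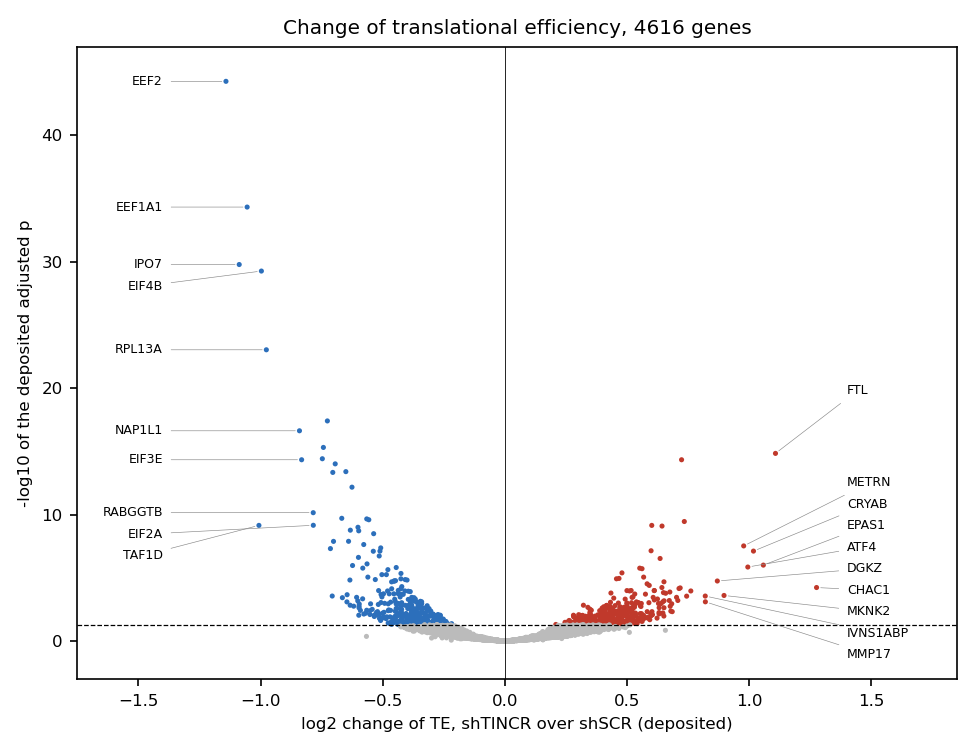
Log2 change of TE (x axis, shTINCR over shSCR) against -log10 of the adjusted p (y axis) for 4616 genes of the authors' deposited table, with the 10 largest rises and falls named. Red points are the 380 genes that rose, blue points the 377 that fell and grey points the 3859 that did not pass the dashed line at 0.05; EEF2, at a log2 change of -1.14, has the smallest adjusted p, and CHAC1, at 1.28, the largest change in size.

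Among the 10 largest rises, CHAC1 and FTL were followed by EPAS1, which encodes the hypoxia factor HIF-2α, at a log2 change of 1.06 (adjusted p = 9.64e-07), and CRYAB, a small heat shock protein, at 1.02 (adjusted p = 7.51e-08) in the authors' deposited table. ATF4 followed at 0.99 and the secreted neurotrophic factor METRN at 0.98 in the authors' deposited table. MKNK2, a kinase that phosphorylates the cap-binding protein eIF4E, rose by 0.90, the diacylglycerol kinase DGKZ by 0.87, and the metalloproteinase MMP17 and IVNS1ABP by 0.82 each on the log2 scale of the authors' deposited table.

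Of the 10 largest falls, 4 were on the list of translation factors and 1 on that of ribosomal proteins. EEF2 fell by 1.14 on the log2 scale (adjusted p = 5.19e-45), EEF1A1 by 1.05 (adjusted p = 4.59e-35) and the initiation factor EIF4B by 0.997 (adjusted p = 5.29e-30) in the authors' deposited table. The ribosomal protein RPL13A had a log2 change of -0.98, the initiation factor subunit EIF3E of -0.83 and EIF2A, an alternative initiation factor, of -0.78 in the authors' deposited table. Outside protein synthesis, the authors' deposited table gave -1.09 for the nuclear import receptor IPO7, -1.01 for TAF1D, a subunit of the RNA polymerase I factor SL1, -0.84 for the histone chaperone NAP1L1 and -0.78 for RABGGTB, a subunit of Rab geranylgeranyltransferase. Of these 10 genes, 5 (EEF2, IPO7, TAF1D, RPL13A and RABGGTB) have genes of small nucleolar RNAs inside them, against 0 of the 10 largest rises.

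**Figure D2:**
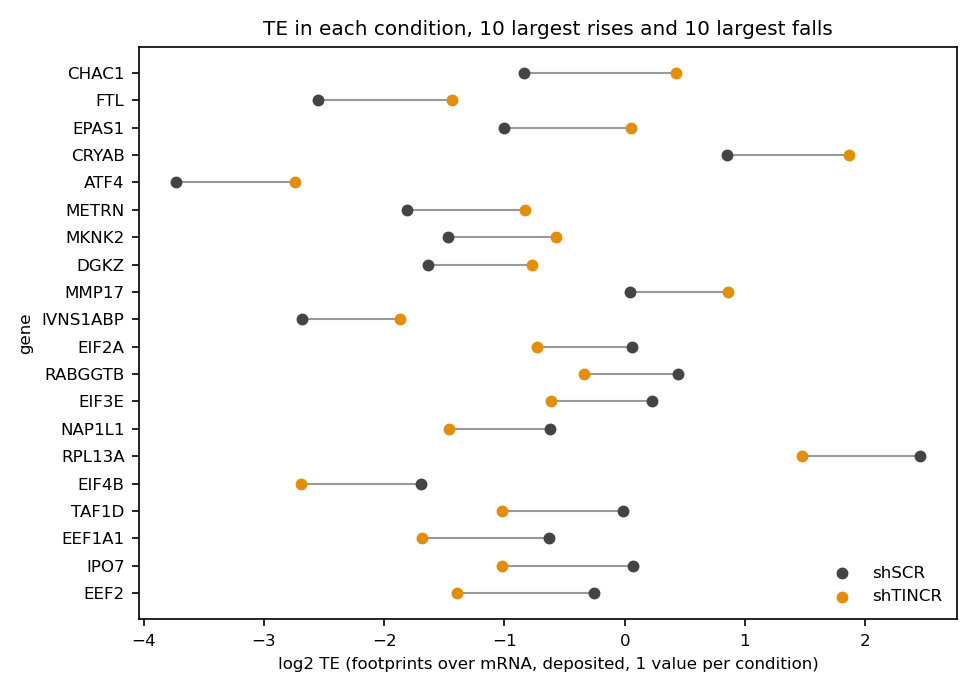
Log2 TE (x axis, footprints over mRNA) in shSCR (grey) and shTINCR cells (orange) for the 10 largest rises and the 10 largest falls in the authors' deposited table, 1 value per condition and no replicate values. Among the rises, TE in shSCR cells ranged from -3.73 for ATF4 to 0.85 for CRYAB; among the falls, from -1.70 for EIF4B to 2.45 for RPL13A.

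Gene lists fixed before the data were examined were then compared with the remaining genes, using limma's camera procedure on the deposited p-values with a preset correlation of 0.01. Of 26 lists, 23 had at least 3 measured members and were tested, and 6 passed at an adjusted p below 0.05. No correlation between genes could be estimated from the table, and higher preset values took its place. The ATF4, ribosomal protein, translation factor and heat shock lists passed at both 0.05 and 0.1. At 0.1 their adjusted p-values were 0.0446, 0.000652, 0.000136 and 0.0458 (camera), so the ATF4 and heat shock lists passed narrowly there.

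Of 28 measured members of the ATF4 and amino acid response list, 11 rose and 0 fell, and 15 rose when adjusted over the list alone. The list's median log2 change was 0.26 (1.20-fold, adjusted p = 2.03e-05, camera). Next to ATF4 and CHAC1, the serine synthesis enzyme PHGDH rose by 0.64 (adjusted p = 7.86e-10), the leucine transporter SLC7A5 by 0.63 (adjusted p = 2.88e-07) and its partner chain SLC3A2 by 0.30 (adjusted p = 0.00804) in the authors' deposited table. The tRNA synthetases WARS and MARS rose by 0.46 and 0.35 and DDIT4, an mTORC1 inhibitor, by 0.40 in the authors' deposited table. Among 7 measured mRNAs of the list of stress mRNAs controlled by upstream reading frames, ATF4, CHAC1 and IBTK rose and 0 fell, and the count adjusted over the list alone was also 3. IBTK, an inhibitor of Bruton's tyrosine kinase, had a log2 change of 0.55 (adjusted p = 0.023) and UCHL5, a deubiquitinase, one of -0.25 (adjusted p = 0.148) in the authors' deposited table. This list's median was -0.03 while its mean was 0.32 and its test pointed up (adjusted p = 0.296, camera). On the log2 change instead of the signed statistic it passed (adjusted p = 0.00797, camera). Without genes that another list holds, 3 members were left and the test pointed down (adjusted p = 0.979, camera). Of 20 measured members of the unfolded protein response list, 3 rose and 1 fell, also when adjusted over the list alone, with a median of 0.06 (adjusted p = 0.386, camera). The transcription factor XBP1 rose by 0.28, the ER proteins SDF2L1 and CRELD2 rose by 0.41 and 0.35, and the chaperone CANX fell by 0.25 in the authors' deposited table.

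Cytosolic ribosomal proteins shifted down as a group. Of 75 measured members 39 fell and 3 rose, or 41 and 4 when adjusted over the list alone, with a median log2 change of -0.23 (0.850-fold, adjusted p = 3.64e-17, camera). Besides RPL13A, the log2 changes in the authors' deposited table were -0.70 for RPS24, -0.69 for RPL5, -0.63 for RPL4, -0.62 for RPL28, -0.54 for RPL38, -0.51 for RPS20 and -0.48 for RPS27. The 3 that rose, named after their values were seen, were RPS15 (0.35), RPS26 (0.29) and RPS2 (0.25) in the authors' deposited table. Of 44 measured translation factors 19 fell and 2 rose, or 21 and 2 when adjusted over the list alone, with a median of -0.17 (0.888-fold, adjusted p = 4.83e-17, camera). TPT1, a growth-related protein, had a log2 change of -0.75, the initiation factor subunits EIF3L and EIF3F of -0.74 and -0.67, and the elongation factor EEF1G of -0.56 in the authors' deposited table. The 2 factors that rose, also named after their values were seen, were the cap-binding inhibitor EIF4EBP1 (0.52) and the heme-regulated eIF2α kinase EIF2AK1 (0.39) in the authors' deposited table. Of the 119 genes of both lists, 100 have named pseudogenes, with which reads can be shared, so single values of these genes are uncertain. Their median was -0.25, and that of the 19 genes with no named pseudogene was -0.06. These groups were not matched on any other trait, so the difference does not by itself show an effect of shared reads.

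Of 33 measured G2/M genes 10 fell and 0 rose, or 12 and 0 when adjusted over the list alone, with a median of -0.20 (0.871-fold). The list passed in the main test (adjusted p = 7.16e-05, camera) but not at a higher preset correlation (adjusted p = 0.0647 with a correlation of 0.1). The mitotic cyclins CCNB1 and CCNB2 fell by 0.48 and 0.43 and their kinase CDK1 by 0.40 on the log2 scale of the authors' deposited table. The kinetochore proteins CENPE and CENPF fell by 0.52 and 0.40, TOP2A by 0.41, the mitotic motor KIF11 by 0.38 and HMMR by 0.35 in the authors' deposited table. Among 33 measured S phase genes 3 fell and 1 rose, also when adjusted over the list alone, with a median of -0.02 (adjusted p = 0.296, camera). The authors' deposited table gave -0.46 and -0.26 for the ribonucleotide reductase subunits RRM1 and RRM2, -0.53 for POLA1, a subunit of DNA polymerase α, and 0.34 for the replicative helicase subunit MCM5. Of 22 measured replication-dependent histone genes 4 rose and 1 fell, also when adjusted over the list alone, with a median of 0.09 (adjusted p = 0.0952, camera). The linker histones HIST1H1E, HIST1H1B and HIST1H1C rose by 0.60, 0.33 and 0.27, HIST1H2AC rose by 0.32 and HIST1H3A fell by 0.30 in the authors' deposited table. Many histone genes, though not all, are near-identical in sequence, so reads can be shared. Histone mRNAs also lack poly(A) tails, which matters only if the RNA, titled as total RNA, was selected for them. These values are therefore uncertain.

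Of 13 measured heat shock genes 6 fell and 1 rose, or 6 and 3 when adjusted over the list alone, with a median of -0.16 (0.897-fold, adjusted p = 0.000935, camera). HSPA8 fell by 0.73 (adjusted p = 3.8e-18), HSPH1 by 0.64, the mitochondrial chaperonin HSPD1 by 0.57, HSP90AB1 by 0.40, CHORDC1 by 0.65 and HSPA4 by 0.32 in the authors' deposited table, against the rise of CRYAB. Whether reads shared with pseudogenes, or reads of small nucleolar RNAs, affect these values was not tested. The list did not pass on ranks (adjusted p = 0.187) or against random lists of the same size (adjusted p = 0.178). Among 18 measured immediate early and AP-1 genes 6 rose and 0 fell, also when adjusted over the list alone, with a median of 0.19 (1.14-fold, adjusted p = 0.0027, camera). That call was lost at a higher preset correlation (adjusted p = 0.098 with a correlation of 0.1) and against random lists matched on TE in shSCR cells (adjusted p = 0.0635). The ETS factor ETV4 rose by 0.65, IER2 by 0.61, PHLDA1 by 0.47, the ERK pathway inhibitors SPRY4 and DUSP4 by 0.33 and 0.26 and cyclin D1 (CCND1) by 0.21 in the authors' deposited table.

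**Figure D3:**
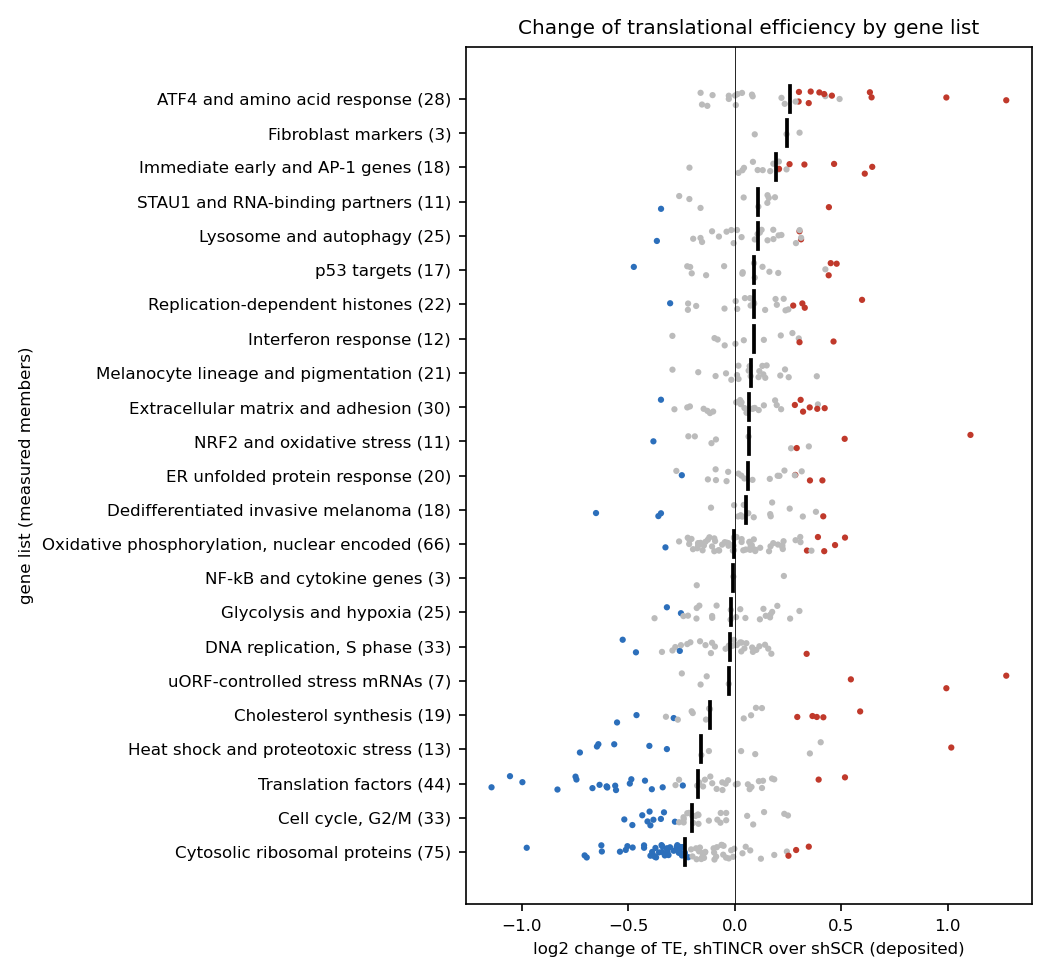
Log2 change of TE (x axis, shTINCR over shSCR, authors' deposited table) of the measured members of 23 gene lists (y axis, number of members in parentheses), ordered by median. Each point is a gene (red rose, blue fell, grey not past adjusted p 0.05; vertical position within a list is random) and the black bar is the list's median, which ran from -0.23 for cytosolic ribosomal proteins to 0.26 for the ATF4 list.

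In the melanocyte lineage list 0 of 21 measured members changed at the deposited adjusted p or when adjusted over the list alone, and 1 had an unadjusted p below 0.05 in the authors' comparison (median 0.07, adjusted p = 0.356, camera). The smallest p-values there belonged to S100A1 (0.25, adjusted p = 0.135), the ion exchanger SLC24A5 (-0.29), the lineage factor SOX10 (0.39, adjusted p = 0.196) and the endothelin receptor EDNRB (0.21) in the authors' deposited table. SOX10 passed in the second version of the authors' estimate (adjusted p = 4.98e-05), and the master regulator MITF, named after its value was seen, stood at -0.04 (adjusted p = 0.80) in the authors' deposited table. Of 18 measured genes of dedifferentiated invasive melanoma 3 fell and 1 rose, or 3 and 2 when adjusted over the list alone, with a median of 0.05 (adjusted p = 0.951, camera). Vimentin (VIM) fell by 0.65 (adjusted p = 3.9e-14), the hyaluronan receptor CD44 by 0.35 and N-cadherin (CDH2) by 0.36, and the neural crest receptor NGFR rose by 0.42 in the authors' deposited table. Of 30 measured extracellular matrix and adhesion genes 6 rose and 1, CD44, fell, or 7 and 3 when adjusted over the list alone (median 0.07, adjusted p = 0.296, camera). This list passed only against random lists matched on the implied standard error (adjusted p = 0.0452). The integrins ITGB5, ITGA3 and ITGB3 rose by 0.39, 0.35 and 0.28, the laminin LAMB2 by 0.42 and the metalloproteinase inhibitors TIMP3 and TIMP2 by 0.32 and 0.31 in the authors' deposited table.

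Of 11 measured NRF2 and oxidative stress genes 3 rose and 1 fell, or 4 and 3 when adjusted over the list alone (median 0.07, adjusted p = 0.296, camera). The ferritin heavy chain FTH1 rose by 0.52 (adjusted p = 9.92e-05) beside FTL, TALDO1 of the pentose phosphate pathway rose by 0.29 and thioredoxin (TXN) fell by 0.38 in the authors' deposited table. FTL and FTH1 have 20 and 27 named pseudogenes, so their values are uncertain. Among 17 measured p53 targets 3 rose and 1 fell, or 3 and 2 when adjusted over the list alone (median 0.09, adjusted p = 0.543, camera). The stress cytokine GDF15 rose by 0.48, PHLDA3 by 0.45 and the cell cycle inhibitor CDKN1A by 0.44, and cyclin G1 (CCNG1) fell by 0.47 in the authors' deposited table.

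Of 19 measured cholesterol synthesis genes 5 rose and 3 fell, or 5 and 5 when adjusted over the list alone (median -0.12, adjusted p = 0.784, camera). Among them, INSIG1, LSS, DHCR7 and SREBF2 rose by 0.59, 0.42, 0.39 and 0.37, whereas MSMO1 and SC5D had log2 changes of -0.55 and -0.46 in the authors' deposited table. Of 66 measured nuclear-encoded oxidative phosphorylation genes 5 rose and 1 fell, or 5 and 0 when adjusted over the list alone. Their median was -0.0028 and their mean 0.03, and the test pointed up (adjusted p = 0.701, camera). NDUFS6, NDUFA1 and NDUFB7 of complex I rose by 0.52, 0.47 and 0.39, UQCR11 and CYC1 of complex III by 0.42 and 0.34, and COX7B of complex IV had -0.32 in the authors' deposited table. Among 25 measured glycolysis and hypoxia genes 2 fell and 0 rose, also when adjusted over the list alone (median -0.02, adjusted p = 0.67, camera), namely LDHA (-0.32) and GAPDH (-0.25) in the authors' deposited table. Whether reads shared with pseudogenes affect the values of LDHA and GAPDH was not tested. Of 25 measured lysosome and autophagy genes 2 rose and 1 fell, also when adjusted over the list alone (median 0.11, adjusted p = 0.296, camera). The lysosomal proteases CTSA and CTSD rose by 0.31 and 0.30 and the proton pump subunit ATP6V1H fell by 0.37 in the authors' deposited table. The mRNAs of the mitochondrial genome had 0 rows in the table and were not analysed here.

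Of 12 measured interferon response genes 2 rose and 0 fell, also when adjusted over the list alone (median 0.09, adjusted p = 0.296, camera). The antigen-presenting HLA-C rose by 0.30 (adjusted p = 0.0153) in the authors' deposited table, a value that is uncertain because reads can be shared with close paralogs. Of 3 measured NF-kB genes 0 changed, also when adjusted over the list alone, and 1, ICAM1 (0.23, adjusted p = 0.112), had an unadjusted p below 0.05 in the authors' deposited table. This list's median was -0.01 and its mean 0.02, with a test that pointed up (adjusted p = 0.951, camera). Among 11 measured members of the list of STAU1, which has been described to bind TINCR, and its RNA-binding partners 1 rose and 1 fell, also when adjusted over the list alone (median 0.11, adjusted p = 0.979, camera). SMG5 of nonsense-mediated decay rose by 0.44 and the helicase DHX9 fell by 0.35 in the authors' deposited table.

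Markers of other cell types were few in the table. Of 3 measured fibroblast markers 0 changed and 0 had an unadjusted p below 0.05 in the authors' comparison (adjusted p = 0.296, camera), with log2 changes of 0.30 for PRRX1, 0.24 for S100A4 and 0.09 for COL1A2 in the authors' deposited table. Of 35 keratinocyte genes 2 were measured, DSP (-0.19) and PERP (0.02, or -0.000351 with the median of all genes subtracted), and 0 changed or had an unadjusted p below 0.05 in the authors' deposited table. Of 20 endothelial and immune markers 2 were measured, KDR (-0.14) and CD68 (0.02), and 0 changed or had an unadjusted p below 0.05 in the authors' deposited table. Counts adjusted over the list alone were also 0 for these 3 lists, and the last 2 lists were too small for the list test.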

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

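The 2 versions of the estimate, the filters on the implied standard error, the higher preset correlations, ranks or the log2 change as the list statistic and matching on the implied standard error were chosen after the data were seen. The count of genes with changed TE moved most with the threshold: 361 genes (167 up, 194 down) at an adjusted p below 0.01, and 8 (4 up, 4 down) with a log2 change of at least 1, both stricter by construction. Among genes with an implied standard error below its median, 210 genes rose, with fewer genes tested, and 308 fell. The remaining settings gave 644 to 1014 genes in total. The 2 versions of the estimate called 828 and 935, which hold all 757 calls by construction, since the final p is the larger of the 2. Subtracting the median of all genes reversed PERP, which was not past the threshold, to -0.000351, and left the sign of the other 132 named genes. In the second version 3 more named genes passed, SOX10, HLA-B and ATP6V0D1. The ATF4, ribosomal protein and translation factor lists passed in all 8 alternatives to the list test, the ATF4 list narrowly at a correlation of 0.1 (adjusted p = 0.0446, camera). The G2/M list was lost at a correlation of 0.1 (adjusted p = 0.0647, range over its alternatives 9.13e-05 to 0.0647). Immediate early genes were lost there (0.098) and with matching on shSCR TE (0.0635; range 0.00258 to 0.098). Heat shock genes were lost on ranks, on the log2 change and against random lists (0.187, 0.145 and 0.141 to 0.251; lowest 0.000894). Upstream reading frame mRNAs were gained on the log2 change (0.00797). Otherwise their adjusted p reached up to 0.979, and their direction turned down without genes that another list holds. Their median also lay on the lower side of random lists, at percentile 34.82, or 27.71 and 20.75 with matching on shSCR TE and on the implied standard error. Extracellular matrix genes were gained with matching on the implied standard error (0.0452, up to 0.687 otherwise). The causes were not tested. The planned fits of library values, filters on level, an estimated correlation and leaving out replicates could not be run without values per library. No paired analysis was possible because the table has no columns of replicates.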

Other observations

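All tests of explanations given here were chosen after the results were seen, except the one on the ATF4 list without ATF4 and CHAC1 and the comparison of the ATF4 list with random lists matched on shSCR TE, which was planned as an alternative list test and only later set against an explanation. Also chosen after were the lists of 5′ TOP factors, symbol families and small nucleolar RNA hosts.

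Families of gene symbols with at least 10 measured members outside the fixed lists gave 0 of 33 past an adjusted p of 0.05 (camera). The RING finger family came closest, with an unadjusted p of 0.0105 and an adjusted p of 0.346 (camera). Of its 15 RNF genes 4 rose and 0 fell, with a median log2 change of 0.21. Among 59 solute carriers 10 rose and 2 fell (median 0.12, adjusted p = 0.347). Of 19 nucleoporins 3 fell and 0 rose (median -0.13, adjusted p = 0.347), and of 23 DEAD-box helicases 6 fell and 1 rose (median -0.07, adjusted p = 0.396). Of 42 mitochondrial ribosomal proteins of the large subunit 3 rose and 0 fell (median 0.08, adjusted p = 0.398), and of 24 of the small subunit 1 rose and 1 fell (median 0.04, adjusted p = 0.809). Outside the ribosomal protein and translation factor lists, 198 genes have small nucleolar RNA genes inside them. Of these hosts 34 fell and 9 rose, with a median of -0.07 at percentile 0.01 of random lists.

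The lower TE of ribosomal protein and translation factor mRNAs had a median log2 change of -0.22 over 119 genes. Reads of small nucleolar RNAs inside the genes do not on their own account for it as a whole, since the 83 members with no such gene inside had a median of -0.20 (percentile 0 of random lists) against -0.24 for the 36 hosts. Reads shared with pseudogenes cannot be told apart from it. The 19 members with no named pseudogene had a median of -0.0572 (percentile 13.5). The 14 with neither a named pseudogene nor a small nucleolar RNA gene had one of -0.04. Both lists together lay below random lists matched on pseudogenes (percentile 0, median of those lists -0.09). That matching took all genes with 5 or more pseudogenes as alike and drew from all genes, members included. It therefore does not decide the question. The 5′ TOP motif, through which mTORC1 controls translation, cannot be judged either. Of 14 factors known as TOP mRNAs 14 fell, against 5 of the 30 other factors (2 rose), with a difference of -0.59 in median log2 change. However, the TOP factors were listed after the ranked genes had been seen. Of 75 ribosomal proteins, also TOP mRNAs, 39 fell, 3 rose and 33 did not pass (median -0.23), while 66 lay below 0 and 9 above. Only 3 of the 14 TOP factors have no named pseudogene, and the other factors had a median of -0.06. The grouping by pseudogenes therefore overlaps with that by TOP mRNAs. Reads shared with pseudogenes, alone or together with those of small nucleolar RNAs, the TOP motif, GC content and an off-target effect of the single hairpin stay open.

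The higher TE of ATF4 pathway mRNAs was not carried by ATF4 and CHAC1 alone, since the 26 other members had a median of 0.23 (percentile 100 of random lists). Nor does a dependence of the change on TE in shSCR cells account for it, with the list at percentile 100 of random lists matched on that TE. Upstream reading frames as a class may contribute, but the 3 members of that list outside the ATF4 list had a median of -0.13 with 1 of 3 above 0, too few and too mixed to decide. Among all 7 measured members, including those shared with the ATF4 list, ATF4, CHAC1 and IBTK lay above 0 and the other 4 below. Most ATF4 targets are known as transcriptional targets, and whether their mRNA also changed cannot be read from a ratio, so a stress response to TINCR silencing and an off-target effect of the hairpin were not tested and stay open.

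The higher TE of FTL, FTH1 and EPAS1 was singled out after these genes were seen to rise, because their mRNAs are known to carry 5′ iron-responsive elements, through which iron regulatory proteins block initiation. No list of such mRNAs was fixed before the data were examined, and the elements as a class are not reported on here. Reads shared with pseudogenes do not account for the rises as a class effect, since 170 other genes with at least 5 named pseudogenes had a median of -0.0752 (quartiles -0.21 and 0.05) and EPAS1 has 0, although the values of FTL and FTH1 stay uncertain for that reason. No biological explanation is weighed here.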
